A study of Mus musculus with 22 samples.

How the data were processed

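Inguinal white fat of male wild-type and PPARα-null mice was measured on Affymetrix whole-transcript mouse arrays, 1 mouse per array. Per the labels all mice spent 5 weeks at 28 °C, after which groups stayed there or moved to 21 °C for 1 week and then to 5 °C for 10 days. The labels give 10 mice housed per group, 40 in all, of which 22 were arrayed: 6 wild-type and 6 null mice at 28 °C, and 5 of each at 5 °C. How these were chosen is not given in the sources used here. Each array took 100 ng of RNA with an integrity number above 8.

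The deposited values are log2 expression values per probe set, made by the authors with RMA (background correction, quantile normalization and median polish). The RMA version and the array's annotation build are not given in the sources used here. All 41345 probe sets were read as deposited, with no further normalization. Arrays have no read depth, so the number of arrays and the signal over background limit the precision. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none in the annotation used here. The brightest probe set over all arrays stood for each of the 1082 genes with more than 1, which left 22180 genes, of which 21994 had a position in a RefSeq gene table on assembly GRCm38.p6. No low-signal filter was applied in the primary fit.

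Genes were tested with limma (3.58.1) under R 4.3.3, with the 4 groups in 1 fit (18 residual degrees of freedom, 3.35 prior degrees of freedom). The 6 comparisons were the cold effect in each genotype, the difference of these effects (null minus wild type), their average, and the genotype effect at each temperature (null minus wild type). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and errors of changes are standard errors from the fit. Values in parentheses after gene names are log2 changes. On simulated data the fit recovered 52%, 92%, 94% and 98% of wild-type cold effects of 0.5, 1, 1.5 and 2 log2 units, and 22%, 68%, 88% and 98% of differences of the cold effects. In each simulation 50 genes of each size were changed at once, which eases the adjusted threshold for the smaller sizes.

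Before the data were examined, 27 gene lists were fixed, 18 of functions and 9 of cell types. They were thermogenic and brown-fat genes, beige-adipocyte genes, PPARα targets, mitochondrial fatty acid oxidation, peroxisomal beta-oxidation, respiratory chain and ATP synthase, tricarboxylic acid cycle, de novo lipogenesis, triglyceride synthesis and lipolysis, glucose uptake and glycolysis, cholesterol synthesis, creatine and calcium cycling, white-adipocyte and adipokine genes, PPAR receptors and coregulators, circadian clock, interferon response, proliferation, and stress and unfolded protein response. The cell types were macrophages, B and T cells, skeletal muscle, epithelium, endothelium, preadipocytes with fibroblasts and matrix, nerve with Schwann cells, mast cells and red blood cells. The 26 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. They were tested again with the correlation estimated from the residuals, and with fry, which asks whether a list's genes move on balance in 1 direction. Red blood cells had 1 measured gene and were not tested.

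Genes are named by a rule fixed before the data were examined. It names Ppara, Ucp1 and Nnt (deleted in part in C57BL/6J) and, in each cold and genotype comparison, the 10 largest called increases and decreases by log2 change, or all where fewer passed. It also names the 10 smallest p in the difference of the cold effects, and in each list up to 4 members with the smallest p plus exceptions to its direction. Predicted genes, microRNAs, small nucleolar RNAs and olfactory and vomeronasal receptors, told by their symbols, are passed over by the rule and count in all numbers of genes.

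Scores per mouse are means of the log2 values of a list, compared with exact two-sided permutation tests over all splits. The difference of the thermogenic scores' cold effects was tested by exchanging genotypes within each temperature, and the 32 cell type score tests were adjusted together. Calls near Ppara were compared with other genes by Fisher's exact test in a window of 10 Mb. Alternatives were another scaling (array medians subtracted, quantile normalization), leaving out the dimmest 25% or 50% of genes, the mean of a gene's probe sets, eBayes with trend and robust, array weights, fitting only the groups compared, an unadjusted p under 0.001, replicate number as a block, windows of 5 and 20 Mb, the score without Ucp1, and leaving out each array in turn. Muscle and lymphocyte scores as covariates were added after seeing the data. For each comparison across genes 100 splits of the arrays, the real one included, were fitted. Tables were handled with the R package data.table (version 1.17.8) and pandas 2.3.3, and figures drawn with matplotlib 3.10.9 under Python 3.11.15. Probe sets without a single gene symbol were left out of the comparisons and fitted on their own.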

Results

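Expression was profiled in inguinal white fat, a subcutaneous depot in which cold can induce heat-producing beige adipocytes. The mice were male, on a C57BL/6 background, and either wild type or lacking PPARα, a nuclear receptor for fatty acids encoded by Ppara. There were 22 whole-transcript arrays, 1 per mouse: 6 wild-type mice kept at 28 °C (thermoneutrality), 5 wild-type mice exposed to 5 °C for 10 days, 6 null mice at 28 °C and 5 null mice at 5 °C. The values were log2 expression values for 41345 probe sets, of which 22180 genes were tested. The highest value of any tested gene on an array was 13.26, and the correlation between any pair of arrays was 0.966 to 0.990. Their number limits the precision. For the genes named here, all 229 called changes of expression between groups had every array of the group compared on the side of the change, beyond the mean of the other group. These changes were picked by the test on the same arrays, so this is no separate support for them. The series asks whether PPARα is needed for browning of this depot in the cold.

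The single Ppara probe set gave 4.72 ± 0.23 log2 units in wild-type mice at 28 °C (mean ± SD, n = 6) and 6.59 ± 0.34 at 5 °C (n = 5). In null mice it gave 4.88 ± 0.43 at 28 °C (n = 6) and 6.30 ± 0.56 at 5 °C (n = 5). Single arrays ran from 4.42 to 5.00, from 6.13 to 6.98, from 4.14 to 5.45 and from 5.77 to 7.10 in these groups. The null minus wild-type difference was 0.16 (SE 0.22, adjusted p = 0.956) at 28 °C and −0.29 (SE 0.24, adjusted p = 0.895) at 5 °C, and neither passed the test. Ppara signal rose with cold by 1.87 (SE 0.23, adjusted p = 3.65e-06) in wild-type mice and by 1.42 (SE 0.23, adjusted p = 0.000129) in null mice. Where these probes lie relative to the disrupted part of the gene is not given in the sources used here, so the probe set does not check the genotype labels.

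The mean of 17 thermogenic and brown-fat genes was used as a score per mouse. It was 5.71 ± 0.14 in wild-type mice at 28 °C (SD, n = 6) and 8.33 ± 0.18 at 5 °C (n = 5), a difference of 2.62. In null mice it was 5.67 ± 0.18 (n = 6) and 8.26 ± 0.18 (n = 5), a difference of 2.59. Each difference had an exact two-sided permutation p of 0.00216 over 462 splits, which is the smallest these splits can give. The cold effects differed by −0.03 between the genotypes (exact permutation p = 0.817 over 232848 arrangements).

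The comparison of cold and thermoneutral wild-type mice asks what the exposure does when the receptor is present. Ucp1, the uncoupling protein of brown-fat mitochondria, rose from 5.35 ± 0.47 to 12.40 ± 0.08 log2 units (SD, n = 6 and 5), a 132-fold change in signal, which is a lower bound if so bright a probe set saturates. Elovl3, a fatty acid elongase, rose from 3.54 ± 0.52 to 10.42 ± 0.45. The oxidase subunits Cox7a1 and Cox8b rose by 3.68 (SE 0.22) and 3.17 (SE 0.18), the acyl-CoA thioesterase Acot11 by 3.54 (SE 0.16), the lipid droplet protein Cidea by 2.67 (SE 0.25) and the proton channel Otop1 by 2.71 (SE 0.25). The other large increases were in Kng2 (3.31), a kininogen, Slc27a2 (3.05), an acyl-CoA synthetase, and Gys2 (2.60), a glycogen synthase. Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose by 2.18.

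The largest decreases in wild-type mice were smaller. Nnat fell from 11.28 ± 0.08 to 9.81 ± 0.65 and Sult1e1, an estrogen sulfotransferase, from 7.51 ± 0.37 to 6.14 ± 0.21 (SD, n = 6 and 5). Ankrd29 (−1.32), Eepd1 (−1.26), the complement component C7 (−1.25), Krtdap (−1.19), the pantetheinase Vnn1 (−1.17), thrombomodulin Thbd (−1.13), the organic anion transporter Slco2b1 (−1.12) and Adamts16 (−1.12) fell as well. Nnt, a mitochondrial transhydrogenase, fell by 0.61 on the log2 scale (SE 0.08, adjusted p = 4.63e-06). In all 3693 genes passed (limma, adjusted p under 0.05), 1852 higher and 1841 lower in the cold, and 179 of the higher and 34 of the lower changed by more than 2-fold. With each array's median subtracted first, 2368 genes were higher and 1354 lower, so the balance of increases and decreases depends on the scaling.

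**Figure D1:**
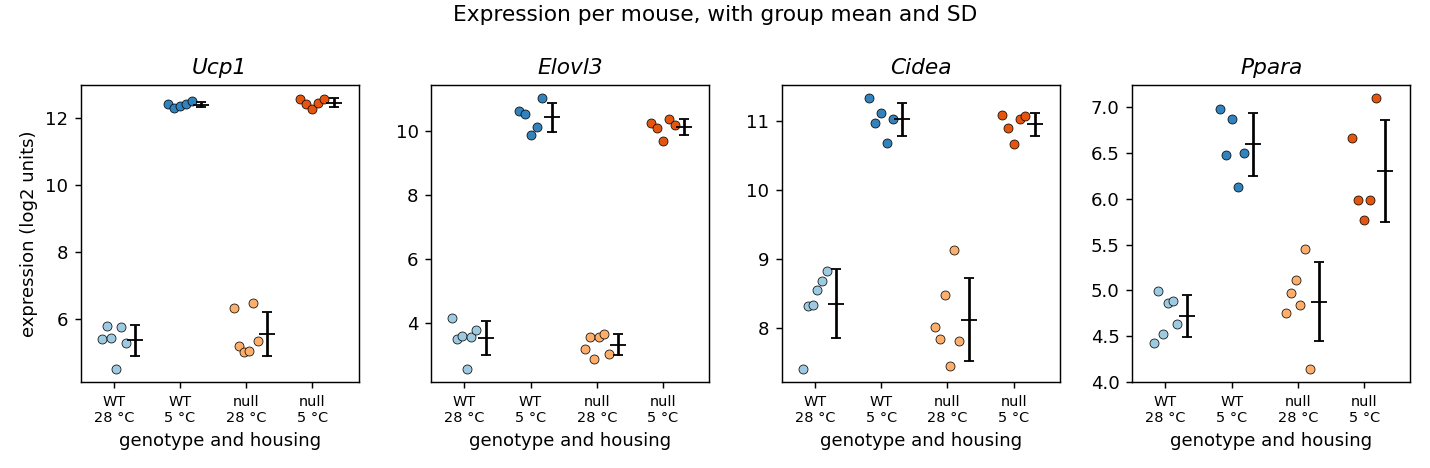
Expression of Ucp1, Elovl3, Cidea and Ppara in log2 units, with 1 point per mouse (6 at 28 °C and 5 at 5 °C in each genotype) and the group mean with SD as a bar beside the points; each panel has its own vertical axis, which does not start at 0. Cold groups lie above the 28 °C groups of the same genotype in all 4 panels, with Ucp1 at 12.40 in wild-type and 12.45 in null mice at 5 °C.

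The same comparison in null mice asks what cold does when the receptor is missing. Ucp1 rose from 5.55 ± 0.66 to 12.45 ± 0.13 log2 units and Elovl3 from 3.34 ± 0.33 to 10.11 ± 0.26 (SD, n = 6 and 5). The next largest increases were in Cox7a1 (3.88), Kng2 (3.39), Acot11 (3.18), Cox8b (2.96), Cidea (2.83), Slc27a2 (2.68), Otop1 (2.60) and Pdk4 (2.58). Sult1e1 fell by 1.91 on the log2 scale (SE 0.20), the decoy interleukin-1 receptor Il1r2 by 1.41 (SE 0.17) and the Wnt inhibitor Sfrp5 by 1.31 (SE 0.29). Saa3 (−1.24), C7 (−1.15), Ifi205 (−1.13), Eepd1 (−1.13), Xpnpep2 (−1.09), Alkal2 (−1.07) and the collagen gene Col1a1 (−1.06) fell too, and Nnt fell by 0.33 (SE 0.08, adjusted p = 0.00411). Here 2930 genes passed, 1525 higher and 1405 lower, with 144 and 19 beyond 2-fold. With array medians subtracted, 1767 were higher and 1039 lower.

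Genes of heat production and fatty acid use rose as groups in both genotypes. Of 17 measured thermogenic and brown-fat genes, 15 rose in wild-type and 14 in null mice (15 and 14 adjusted over the list alone), with median changes of 2.67 and 2.60. Letmd1, a mitochondrial inner membrane protein, rose by 1.82 and 1.91. Prdm16, a coregulator of brown adipocyte identity, rose by 0.43 in wild-type mice (adjusted p = 0.00281) and was 0.08 higher in null mice (adjusted p = 0.698). Its difference between genotypes, −0.36 (SE 0.14), did not pass (adjusted p = 0.963). Of 17 mitochondrial fatty acid oxidation genes, 16 rose in each genotype (16 and 16 adjusted over the list alone, with 1 lower in wild-type mice), among them the carnitine carrier Slc25a20 (2.03 in wild-type, 2.20 in null mice), Etfdh (1.37 and 1.23), Hadha (1.43 and 1.39) and Acadl (1.26 and 1.37). Cpt1a, the liver-type carnitine palmitoyltransferase, was the exception, at −0.36 (adjusted p = 0.0578) and −0.03. Of 15 peroxisomal oxidation genes, 12 and 11 rose (13 and 13 adjusted over the list alone), with the transporter Abcd3 at 1.10 and 0.94 and Hsd17b4 at 0.66 and 0.56.

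Known PPARα target genes rose in the null mice too. Of 35 measured, 21 rose and 1, Vnn1, fell in wild-type mice, and 20 rose and 0 fell in null mice. Adjusted over the list alone, 22 rose and 2 fell in wild-type mice, and 22 rose in null mice. The median change was 0.54 and 0.46, and 19 of the 35 genes also stand in another list, mostly that of fatty acid oxidation. Vnn1 differed between genotypes in its cold effect by 0.84 (SE 0.41), which did not pass (adjusted p = 0.963). Of 13 PPAR receptors and coregulators, 5 rose in wild-type and 6 in null mice (6 and 7 adjusted over the list alone), among them the coactivator Ppargc1b (1.48 and 1.47), the retinoid receptor Rxrg (0.68 and 0.69) and the estrogen-related receptor Esrra (0.80 and 0.53).

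Genes of mitochondrial respiration and of fuel supply also rose. All 45 measured genes of the respiratory chain and ATP synthase rose in both genotypes (45 and 45 adjusted over the list alone), with Uqcrfs1 at 1.28 and 1.29 and Ndufv1 at 1.02 and 0.98. All 19 tricarboxylic acid cycle genes did so (19 and 19 adjusted over the list alone), with Suclg1 at 1.43 and 1.41 and Dlat at 1.64 and 1.52. Of 16 genes of glucose uptake and glycolysis, 11 rose in wild-type and 12 in null mice (11 and 12 adjusted over the list alone), such as the monocarboxylate carrier Slc16a1 (1.78 and 1.38) and the phosphofructokinase Pfkl (1.70 and 1.54). Of 20 genes of triglyceride synthesis and lipolysis, 10 and 8 rose (10 and 12 adjusted over the list alone), such as the acyltransferase Agpat2 (1.16 and 0.98) and Gpd1 (1.09 and 0.97). Of 15 lipogenic genes, 10 rose in each genotype (12 and 10 adjusted over the list alone), such as Me1 (1.03 and 1.00) and Elovl6 (1.33 and 1.61). That list passed with the preset correlation, with adjusted p = 0.0914 in wild-type and adjusted p = 0.0743 in null mice with an estimated correlation. Of 14 cholesterol synthesis genes, 11 and 6 rose (12 and 9 adjusted over the list alone, with 1 of the null genes lower), such as Hmgcs1 (1.31 and 1.01), and the list's adjusted p was 0.106 and 0.190 with an estimated correlation.

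Markers of macrophages and of matrix-producing cells fell in both genotypes. Of 17 macrophage markers, 13 fell in each (15 and 15 adjusted over the list alone), with the complement gene C1qb at −0.72 and −0.61, the mannose receptor Mrc1 at −0.70 and −0.63 and Csf1r at −0.65 and −0.53. The mean of these markers was lower by 0.58 and 0.53 log2 units in the cold (exact permutation p = 0.00216 each, the smallest possible, adjusted p = 0.0173 over 32 such tests). Of 16 markers of preadipocytes, fibroblasts and matrix, 12 fell in each genotype (14 and 13 adjusted over the list alone), with Col1a2 at −0.83 and −0.90 and Col3a1 at −0.70 and −0.74. Muscle and lymph node markers varied between pads but did not pass with cold. The median of 16 muscle markers changed by −0.63 in wild-type and 0.48 in null mice, and that of 13 B and T cell markers by −0.62 and −0.80, with 0 of them called by limma in either genotype and camera adjusted p = 0.0715 and 0.472 for muscle and 0.110 and 0.0734 for B and T cells.

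In all, 17 of 26 tested lists passed in wild-type mice with camera's preset correlation and 15 in null mice. With the correlation estimated from the data 11 held in each: thermogenic genes, PPARα targets, both fatty acid oxidation lists, the respiratory chain, the tricarboxylic acid cycle, triglyceride synthesis, glycolysis, PPAR receptors, macrophages and matrix. By fry 17 and 16 lists passed, the 1 added in null mice being beige-adipocyte genes. With the preset correlation, 15 of 100 regroupings of the wild-type arrays and 22 of 100 of the null arrays, the real ones included, gave as many lists, and with the estimated correlation 1 and 2 did.

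**Figure D2:**
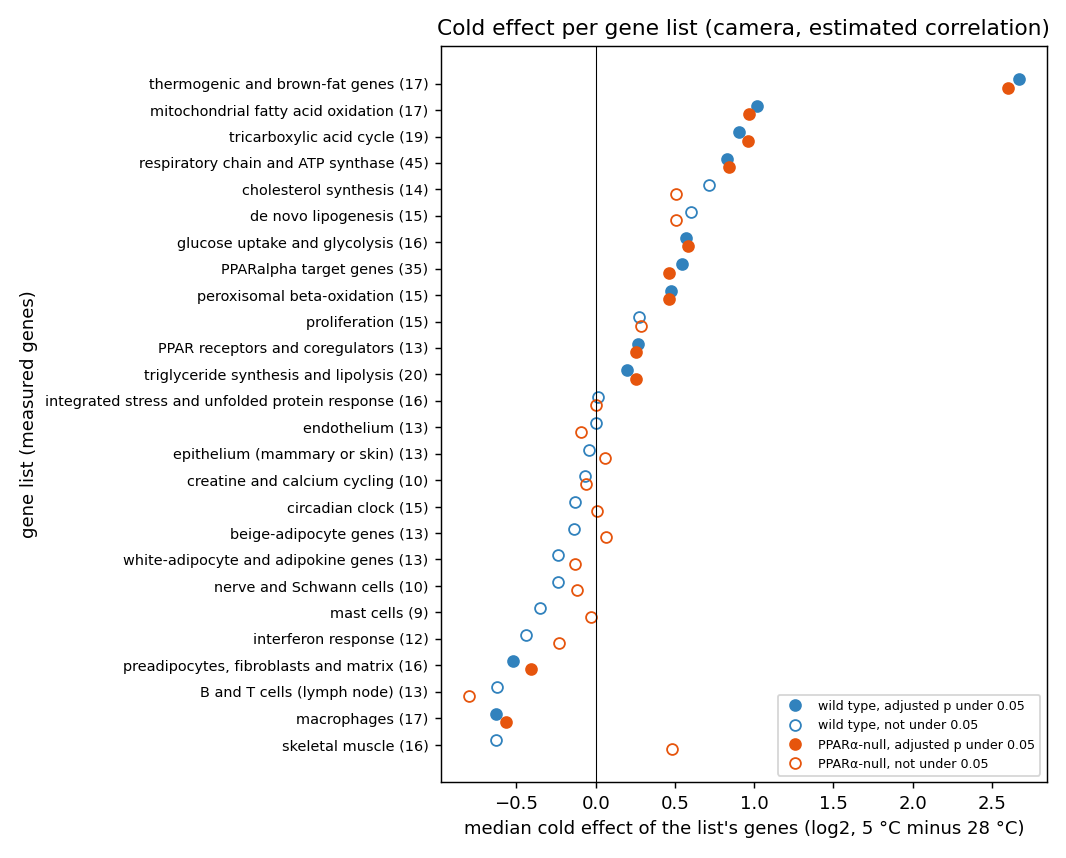
Median cold effect (log2, 5 °C minus 28 °C, horizontal axis) of the measured genes of each list, whose number stands in brackets, with wild-type mice in blue and null mice in orange. Filled points are lists with an adjusted p under 0.05 by camera with an estimated correlation, 11 in each genotype; thermogenic genes lie at 2.67 and 2.60.

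The comparison of the cold effects between the genotypes asks directly whether the response needs the receptor. The cold effect on Ucp1 was 7.05 in wild-type and 6.90 in null mice, a difference of −0.14 (95% interval −0.86 to 0.58). For Elovl3 the difference was −0.10 (−0.77 to 0.58), for Cidea 0.16 (−0.56 to 0.88), for Cox7a1 0.20 (−0.44 to 0.85), for Slc25a20 0.17 (−0.16 to 0.51) and for Ppara itself −0.45 (−1.12 to 0.22). By limma 0 of 22180 genes passed, the smallest adjusted p was 0.688, and 1137 genes (5.13%) had an unadjusted p under 0.05. With the predicted genes, microRNAs and olfactory receptors that the naming rule passes over left out, the 10 genes with the smallest p, none of which passed, were Mctp1 (0.52), Swsap1 (−0.67), H2-Q10 (0.60), Nos2 (−0.72), Prdm12 (0.87), Gtse1 (−0.95), Zfp110 (0.45), Zfp981 (−0.85), Tff3 (0.55) and Ramp3 (0.53). Among the 5499 genes called in the average of the cold effects, 97.5% had a 95% interval of the difference within 1 log2 unit of 0. This bound alone does not show that the response was kept, since 179 genes rose and 34 fell by more than 2-fold in wild-type mice. For most genes a full loss of the cold effect would also lie within it. A difference of 1 log2 unit or less could go undetected, since 22% of simulated differences of 0.5 log2 units and 68% of those of 1 were recovered. With 50 genes of each size changed at once, these shares may exceed those for a lone gene.

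The smallest p of all genes in this comparison belonged to 2310069B03Rik, a predicted gene outside the naming rule that was named after its values were seen. It went from 3.74 ± 0.23 at 28 °C (SD, n = 6) to 6.17 ± 0.50 at 5 °C (n = 5) in wild-type mice and from 3.67 ± 0.13 (n = 6) to 4.85 ± 0.28 (n = 5) in null mice. Its cold effects of 2.42 and 1.18 both passed, with 5 of 5 cold arrays higher in each genotype. Their difference of −1.24 (SE 0.25, 95% interval −1.76 to −0.73) did not pass over all genes (adjusted p = 0.688), but did without wild-type 5 °C replicate 3 (−1.43, adjusted p = 0.0214). The genotype difference did not pass at 28 °C (−0.07, adjusted p = 0.981), and null mice were lower at 5 °C (−1.32, adjusted p = 0.000624), a call that held without any single array (−1.50 to −1.16, adjusted p at most 0.00322).

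The list of thermogenic genes had a median difference of −0.05 (adjusted p = 0.829), and 0 of its 17 genes passed (0 adjusted over the list alone). That of PPARα targets had a median of −0.01 and a mean of 0.05, with a test that pointed up (adjusted p = 0.829). Of 26 lists, 2 passed with the preset correlation, and both hold markers of other cell types. Skeletal muscle markers had a median difference of 1.07 (camera adjusted p = 0.00104, and adjusted p = 0.972 with an estimated correlation). Mast cell markers had a median difference of 0.50 (camera adjusted p = 2.33e-05, and adjusted p = 0.516 with an estimated correlation). Without null 5 °C replicate 1 only 1 list passed.

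The size of the response was compared across genes. Over all genes the cold effects in null and wild-type mice had r = 0.738, and genes are not independent replicates. Over the genes called in the average effect r was 0.942, which is raised by that choice of genes. Among these 5499 genes the median ratio of the null to the wild-type effect was 0.913, with quartiles of 0.686 and 1.17. Of genes called in the cold effect of each genotype, 1190 were higher in both (127 expected from independent lists), 999 were lower in both (117 expected) and 0 were called in opposite directions. Both sets of calls come from 1 fit with a shared variance per gene, so the expected numbers are only a loose reference. Of the 3693 genes called in wild-type mice, 3548 (96.1%) had the same sign in null mice, and of the 2930 called in null mice 2884 (98.4%) had the same sign in wild-type mice. The average effect itself called 2586 genes higher and 2913 lower, or 3325 and 2206 with array medians subtracted.

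**Figure D3:**
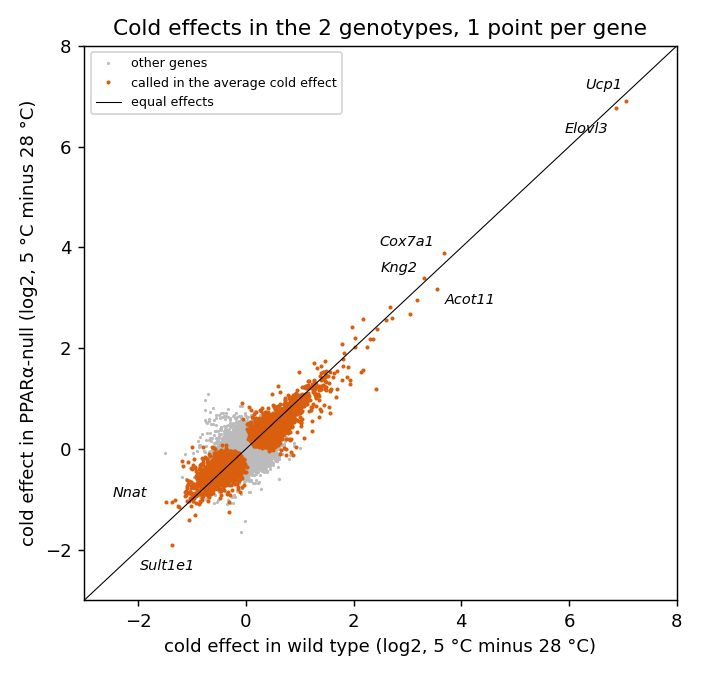
Cold effect in null mice (vertical axis) against that in wild-type mice (horizontal axis), both as log2 of 5 °C minus 28 °C, with 1 point per gene for 22180 genes. Orange points are the 5499 genes called in the average cold effect and the line marks equal effects; Ucp1 lies at 7.05 and 6.90.

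The comparison of genotypes at 28 °C asks how null and wild-type mice differ without cold. It cannot tell loss of the receptor from other sequence differences between the genotypes, on any chromosome. Ifi44l, an interferon-induced gene, was at 1.89 ± 0.25 log2 units in wild-type and 4.95 ± 0.55 in null mice (SD, n = 6 each), and Rpl3, a ribosomal protein gene, at 7.91 ± 0.37 and 10.23 ± 0.06. The wild-type mean of Ifi44l lay below the lower quartiles of the arrays (2.83 to 2.91), close to background, so the size of its difference is uncertain. Hdhd3 (1.09), the heme synthesis enzyme Alad (1.00), the prostaglandin F receptor Ptgfr (0.91), Ppwd1 (0.79), Cdh9 (0.69), Lrg1 (0.52) and Dap (0.50) were higher in null mice. Lower in null mice were Cmtm8 (−1.31), albumin Alb (−1.27), the cytochrome b5 reductase Cyb5r3 (−1.25), Cmbl (−1.16), Ranbp3l (−1.14), the oxidase subunit Cox7c (−1.13), the lipid droplet enzyme Pnpla3 (−1.12), Ift27 (−1.08), insulin-degrading enzyme Ide (−1.07) and the Polycomb gene Cbx7 (−0.99). Ucp1 differed by 0.20 (SE 0.23, adjusted p = 0.938) and Nnt by −0.01 (SE 0.07, adjusted p = 0.990). In all 43 genes passed, 10 higher and 33 lower, including some that the naming rule passes over, such as the small nucleolar RNA Snord123 (−1.12 at 28 °C and −1.13 at 5 °C), which was named after its values were seen. The call of Pnpla3 ended without wild-type replicates 1, 4 or 6 or null replicate 2 (adjusted p = 0.0610 to 0.0702). Fitted on these groups alone, Pnpla3 (adjusted p = 0.165), Cdh9 (adjusted p = 0.0734) and Dap (adjusted p = 0.0903) did not pass, and with muscle and lymphocyte scores as covariates neither did Hdhd3 (1.08, adjusted p = 0.0530) and Pnpla3 (−0.94, adjusted p = 0.199), whose changes stayed similar.

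As groups, 8 lists were lower in null mice at 28 °C with the preset correlation, and 0 of them passed with an estimated correlation or by fry. Muscle markers had a median of −1.59 (camera adjusted p = 1.04e-09, and adjusted p = 0.603 with an estimated correlation), and their mean per mouse differed by −1.33 (exact permutation p = 0.0260, adjusted p = 0.139 over 32 tests). Beside them the medians were −0.07 for mitochondrial fatty acid oxidation, the respiratory chain and the tricarboxylic acid cycle, −0.13 for peroxisomal oxidation, −0.04 for PPARα targets, −0.18 for lipogenesis and −0.32 for mast cells. Camera adjusted p was 0.00234, 0.000123, 0.00639, 0.00234, 0.00779, 0.00243 and 0.000123 in that order, and adjusted p = 0.809, 0.817, 0.823, 0.740, 0.740, 0.740 and 0.603 with an estimated correlation. Among the members of these 8 lists 1 gene, Pnpla3, was called (adjusted over the list alone: 1 in lipogenesis, 1 in the tricarboxylic acid cycle, 4 mast cell markers and 0 in the others).

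At 5 °C the same comparison asks how the genotypes differ in the cold, with the same limit. Ifi44l was at 1.98 ± 0.26 in wild-type and 4.33 ± 0.22 in null mice (SD, n = 5 each), and Rpl3 at 7.58 ± 0.17 and 9.73 ± 0.18. The wild-type mean of Ifi44l was again close to background. Ptgfr (1.27), Cdh9 (0.94), Alad (0.90), Ppwd1 (0.72), Sema5a (0.66) and Dap (0.49) were higher in null mice. Lower were Cmtm8 (−1.37), Cyb5r3 (−1.16), Cmbl (−1.08), Ide (−0.97), Clec3b (−0.94), Cox7c (−0.89), Ccdc149 (−0.87), Lynx1 (−0.69), Cyp2d22 (−0.68) and the endothelial nitric oxide synthase Nos3 (−0.68), beside the predicted gene 2310069B03Rik (−1.32). Ucp1 differed by 0.05 (SE 0.26, adjusted p = 0.988) and Nnt by 0.26 (SE 0.08, adjusted p = 0.360). In all 33 genes passed, 9 higher and 24 lower, and 19 passed when these groups were fitted alone. Of the genes named, those that did not pass then were Ccdc149 (adjusted p = 0.304), Cyp2d22 (0.277), Sema5a (0.227), Clec3b (0.200), Cox7c (0.151) and Nos3 (0.0695), with the same log2 changes. With muscle and lymphocyte scores as covariates Clec3b did not pass (adjusted p = 0.0695), at −0.94 as before.

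Of the genes named at 5 °C, 5 had calls close to the threshold, which ended on leaving out any of several arrays while their log2 changes stayed similar. The call of Clec3b ended without any wild-type replicate or null replicates 2, 3 or 5 (adjusted p = 0.0540 to 0.137, changes of −0.99 to −0.81), and that of Ccdc149 without wild-type replicates 2 to 5 or null replicates 2, 4 or 5 (0.0555 to 0.102, −0.91 to −0.69). That of Cyp2d22 ended without wild-type replicates 1, 4 or 5 or null replicates 1 or 3 (0.0879 to 0.105, −0.67 to −0.58), that of Nos3 without wild-type replicates 1 or 5 or null replicates 1, 3 or 4 (0.0555 to 0.0720, −0.66 to −0.63), and that of Sema5a without wild-type replicates 1, 4 or 5 or null replicates 1, 2 or 5 (0.0749 to 0.102, 0.57 to 0.66). As groups, peroxisomal oxidation (median −0.08), mitochondrial fatty acid oxidation (−0.10), lipogenesis (−0.12) and cholesterol synthesis (−0.17) were lower with the preset correlation (adjusted p = 0.00272, 0.00807, 0.00790 and 0.0114), with 0 members called (2, 1, 1 and 0 adjusted over the list alone). Each had adjusted p = 0.707 with an estimated correlation. Muscle markers had a median of −0.45 (camera adjusted p = 0.345). The count of 4 lists was 1 without null replicate 2 or wild-type replicates 1 or 5, and 7, 8 and 9 without wild-type replicate 2, wild-type replicate 3 and null replicate 1.

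The genotype calls were compared with each other and with the position of Ppara. There were 50 genes called at 28 °C or 5 °C, 26 of them at both (0.064 expected from independent lists), and 48 of the 50 had the same sign at both temperatures. These calls also share the variance per gene of 1 fit, so the expected number is only a loose reference. In the order of genes on assembly GRCm38.p6, 21 of the 49 calls with a position lay on chromosome 15, which also holds Ppara, including Rpl3, Cyb5r3, Cmbl, Ift27, Cbx7, Pnpla3, Ranbp3l, Lynx1, Cdh9 and Dap. Within 10 Mb of Ppara lay 11 of the 49 calls (22.4%) and 309 of 21944 other genes (1.41%), an odds ratio of 20.3 (95% interval 9.25 to 40.9, two-sided Fisher's exact p = 9.28e-11). The odds ratio was 17.6 within 5 Mb (5 calls, Fisher's exact p = 1.81e-05) and 12.03 within 20 Mb (12 calls, Fisher's exact p = 4.46e-09), so 9 of the 21 calls on the chromosome lay over 20 Mb from Ppara. For the whole chromosome, tested after the gathering was seen, it was 19.4 (95% interval 10.4 to 35.5). The windows therefore do not show that calls gather nearer Ppara than elsewhere on chromosome 15.

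**Figure D4:**
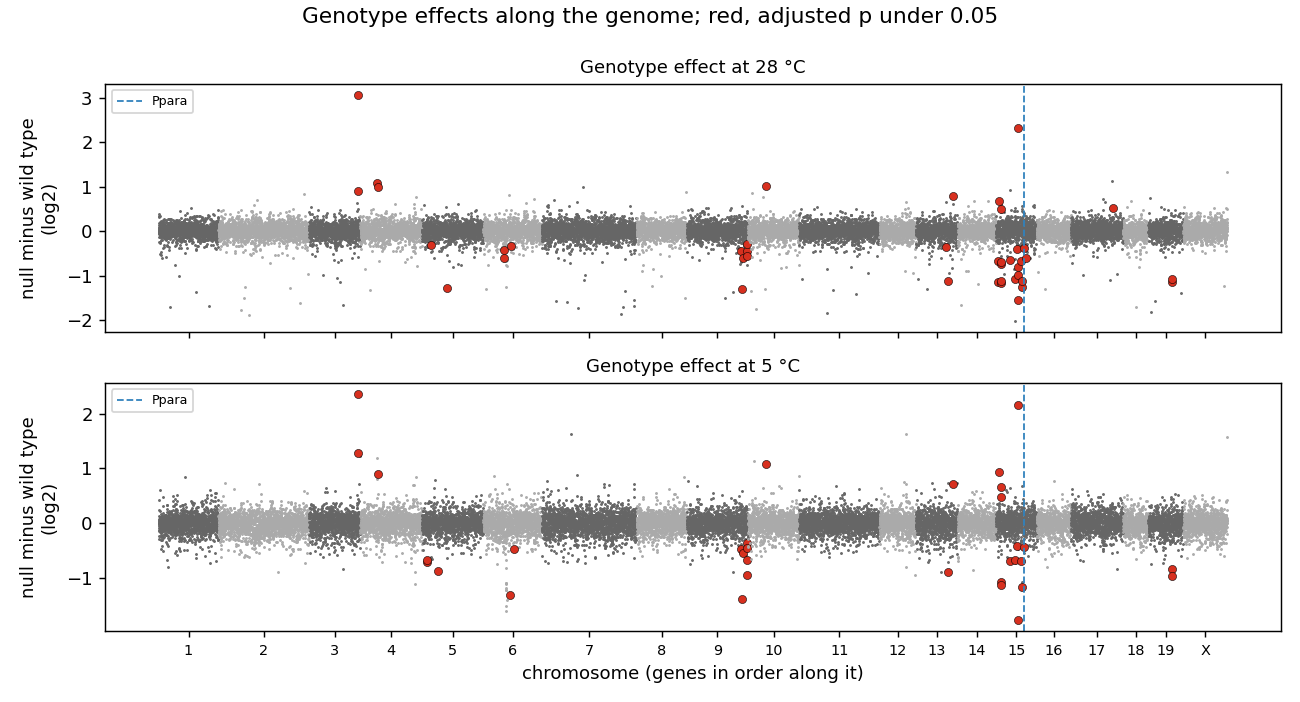
Null minus wild-type difference in log2 units (vertical axes) at 28 °C and at 5 °C for each gene with a position, in gene order along the chromosomes (horizontal axis), with called genes in red (43 and 33 in all) and the place of Ppara as a dashed line. Calls gather on chromosome 15, which holds 21 of the 49 placed genes called at either temperature.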

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

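The tests against linked alleles, receptor loss, probe mismatch in genes higher in null mice, muscle and lymph node content, saturation of brighter genes, too few arrays and a transcript part still made were chosen only after the result was seen. Of 464 groups of the genes named in the text, 22 held an array far from the rest by Dixon's ratio; chance gives about 1 in 20 groups, or 23.2 here. In wild-type mice at 28 °C these were replicate 1 for C7 (0.667), Cidea (0.643), Col1a1 (0.639), Col1a2 (0.634) and Cry1 (0.672), replicate 2 for Cmtm8 (0.625), replicate 3 for Sp100 (0.662), replicate 4 for Dap (0.721) and Lrrfip2 (0.652), and replicate 6 for Tek (0.669). In wild-type mice at 5 °C they were replicate 1 for Ppargc1b (0.761), Rpl3 (0.744) and Slc16a1 (0.711), replicate 2 for Zfp110 (0.814) and replicate 3 for Me1 (0.724). In null mice they were replicate 3 at 28 °C for Alad (0.658) and Nnt (0.773), replicate 4 at 28 °C for Mctp1 (0.674), replicate 5 at 28 °C for Snord123 (0.670), replicate 3 at 5 °C for Col1a1 (0.717) and Sp100 (0.754), and replicate 4 at 5 °C for Ppwd1 (0.778). Among 36 groups of list scores 0 held such an array. Genes are not independent of each other, so arrays with several such genes do not count as several findings.

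Cold effects differed between the genotypes for skeletal muscle markers (camera adjusted p = 0.00104) and mast cell markers (2.33e-05) with the preset correlation, but not with an estimated one (adjusted p = 0.972 and 0.516). In the fit of the 17824 probe sets without a single gene symbol, 457 passed for cold in wild-type mice, 258 for cold in null mice, 12 for genotype at 28 °C and 11 for genotype at 5 °C. For the difference of the cold effects 1 passed, probe set 17528348, at −1.84 (SE 0.28, adjusted p = 0.0305). Its mean went from 2.09 to 3.07 in wild-type mice and from 3.00 to 2.14 in null mice. These means lie near or below the lower quartiles of the arrays, which ran from 2.83 to 2.91, so its signal is close to background. Its adjusted p is over the 17824 probe sets alone, not over all probe sets of the array.

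The genotype calls gathered on chromosome 15. If loss of the receptor's activity were the source of the excess, calls would be expected on chromosomes in proportion to their genes. The lower bound of the chromosome's odds ratio was 10.4, but this value restates the gathering that prompted the question and is no separate test of that source. Probes that mismatch donor-strain sequence would lower the signal, which 4 calls on this chromosome that were higher in null mice argue against for those genes; for lower genes 17 of 21 calls were lower there and 21 of 28 elsewhere (Fisher's exact p = 0.737), which leaves mismatch open. Donor-strain alleles linked to the disrupted gene are a candidate explanation. The odds ratio was 20.3 within 10 Mb, 17.6 within 5 Mb and 12.03 within 20 Mb, beyond which 9 of the 21 calls on the chromosome lay. For the whole chromosome it was 19.4, so the windows do not show that calls gather nearer Ppara than elsewhere on the chromosome. Genotype effects of the genes called on chromosome 15 may come from linked sequence and not from the receptor. For the calls elsewhere the receptor's role was not tested, and other sequence differences between the genotypes cannot be told apart from it.

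By limma 0 genes were called in the difference of the cold effects, with 1137 at an unadjusted p under 0.05. Saturation of bright probe sets could hardly act on the 4776 cold-called genes below 9 log2 units, since the highest value of any gene was 13.26. Their median ratio of effects was 0.905, which cannot show whether saturation hides a difference in brighter genes. Saturation stays open for the 723 brighter ones, such as Ucp1. With muscle and lymphocyte scores as covariates the smallest adjusted p was 0.483, and 1371 genes (6.18%) had an unadjusted p under 0.05. The intervals exclude a difference over 1 log2 unit for 97.5% of cold-called genes, while too few arrays stays open for the other 136 and for genes such as 2310069B03Rik, at −1.24 (adjusted p = 0.688). On simulated data 22% of differences of 0.5 log2 units and 68% of those of 1 were recovered, so differences of these sizes may have been missed, and a biological absence stays a hypothesis. The shares hold for 50 genes of each size changed at once and may be lower for a lone gene.

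The Ppara probe set was not lower in null mice. Mislabelled genotypes of single arrays are argued against by a score of the genes called at the other temperature, which put 0 of 22 arrays with the other genotype. A swap of all genotype labels would pass this test and stays open. Probes that read a part of the transcript still made in null mice may explain it, in line with the probe set's cold effect of 1.42 in those mice.

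Over 100 regroupings of the arrays, the real one included, chance is argued against for the genes called by cold in each genotype. The counts were 3693 in wild-type mice (highest other 2248) and 2930 in null mice (1718). The same held for the average cold effect (5499, 499) and for genotype at 28 °C (43, 0) and 5 °C (33, 2). In each case only the real grouping gave as many, and 100 regroupings can show a share no smaller than 1 in 100. For the difference the real count is 0 (highest other 18), which all 100 regroupings reach by definition, so they decide nothing there. For lists with the preset correlation chance stays open for cold, with 17 in wild-type mice (highest other 18, 15 as large) and 15 in null mice (18, 22 as large). So it does for 2 lists in the difference (13, 86 as large), 8 at 28 °C (15, 40 as large) and 4 at 5 °C (14, 58 as large). Highest counts several times the real one, as in the difference and at 5 °C, point to a structure among the arrays, or to a correlation between genes above the preset one, which were not tested against each other; with an estimated correlation the highest counts there were 1 and 0. With the estimated correlation 11 lists passed for cold in wild-type mice (highest other 10, 1 as large) and 11 in null mice (highest other 11, 2 as large). Few regroupings gave as many, which argues against chance. Another regrouping of the null arrays gave the same 11, so chance is not excluded. For the difference (highest other 1) and for genotype at 28 °C (1) and 5 °C (0) the real number is 0, which all 100 reach by definition, so the regroupings decide nothing.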

How the results depend on the processing

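Muscle and lymphocyte scores as covariates were the test chosen only after the result was seen. Counts of called genes stayed within 1.5 times under another scaling, filter on dim genes, variance model, array weights and probe set mean. At an unadjusted p under 0.001 they were 2249 (cold in wild-type mice), 1799 (cold in null mice), 24 (difference), 3417 (average), 86 (genotype at 28 °C) and 91 (genotype at 5 °C), by the construction of that threshold, and 19 for genotype at 5 °C with only the groups compared, which leaves fewer samples to estimate the spread. Across genes r was 0.892 without the dimmest 50%. With an estimated correlation 11 lists passed for cold in wild-type and 11 in null mice, and 0 for the difference and for genotype at 28 °C and 5 °C. By fry the numbers were 17, 16, 0, 0 and 0. Genotype at 5 °C gave 7 lists without the dimmest 50% of genes, and the cause was not tested. With the covariates the counts were 3681, 2913, 0, 5242, 44 and 36. Of 217 called results of the genes that the naming rule picks, 193 were called under every setting run and 0 reversed. This set is not that of the 229 called changes of the genes named in the text. The rule also picks genes not named there, but counts a gene only in the comparisons it was picked for. The 229 count each gene of the text in every cold effect of a genotype and every genotype effect that called it. Signal over background limits dim genes.

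Leaving out each array in turn gave 3150 to 3571 genes for cold in wild-type mice, 2320 to 2802 in null mice, 0 to 1 for the difference (1 without wild-type 5 °C replicate 3), 5136 to 5467 for the average, 31 to 45 at 28 °C and 23 to 36 at 5 °C. The correlation was 0.698 to 0.742 and the median ratio 0.870 to 0.964. Lists numbered 16 to 19 in wild-type mice, 15 to 17 in null mice, 1 to 3 for the difference (1 without null 5 °C replicate 1), 6 to 10 at 28 °C and 1 to 9 at 5 °C (9 without null replicate 1, 8 and 7 without wild-type replicates 3 and 2, 1 without null replicate 2 or wild-type replicates 1 or 5). The score's cold effect was 2.57 to 2.67 in wild-type and 2.53 to 2.65 in null mice (exact p at most 0.00794). Its difference of −0.03 ran from −0.0947 to 0.0299 and changed sign without null 5 °C replicate 3 (0.0299), null 28 °C replicate 5 (0.0119), wild-type 5 °C replicates 1 (0.0213) and 5 (0.00482) and wild-type 28 °C replicate 3 (0.00568), with exact p of at least 0.831.

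With replicate number as a replicate block the counts were 3512, 2683, 0, 5125, 34 and 28 in the order above. Residuals of arrays with the same number correlated at −0.25 to 0.35, so the numbers do not pair the samples.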

Other observations

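The test of each chromosome was chosen only after the result was seen. Several lists showed few called genes or no common direction in the cold, in the limma fit. Of 13 beige-adipocyte genes, 3 rose and 2 fell in wild-type mice and 4 rose and 2 fell in null mice (3 and 3, and 4 and 4, adjusted over the list alone). A decrease in null mice did not pass without null 5 °C replicates 1 or 2 or null 28 °C replicates 1 or 2 (limma adjusted p = 0.0532 to 0.0780). The purine receptor P2rx5 rose by 1.93 and 1.37 and the amino acid transporter Slc36a2 by 0.89 and 0.92, while Sp100 fell by 0.57 and 0.42 on the log2 scale. The list's median changes were −0.14 and 0.06 (camera adjusted p = 0.960 and 0.570, fry adjusted p = 0.0969 and 0.0218), and in wild-type mice the mean (0.05) and the test had the opposite sign to the median. Of 10 genes of creatine and calcium cycling, 2 rose and 1 fell in each genotype (2 and 2 in each adjusted over the list alone), with the calcium pump Atp2a2 at 0.44 and 0.42, Pm20d1 at 0.73 and 0.97 and Gatm at −0.58 and −0.52. The medians were −0.07 and −0.06 (camera adjusted p = 0.872 and 0.570), whereas the test pointed up in both genotypes and the mean was −0.04 and 0.05. Of 16 genes of the stress and unfolded protein response, 3 rose and 3 fell in wild-type mice and 2 rose and 1 fell in null mice (3 and 3, and 2 and 2, adjusted over the list alone), with asparagine synthetase Asns at 0.68 and 0.67 and medians of 0.01 and 0.00 (camera adjusted p = 0.868 and 0.986). An increase in null mice did not pass without null 5 °C replicates 2, 4 or 5 or null 28 °C replicate 1 (limma adjusted p = 0.0519 to 0.0978). Of 15 clock genes, 0 passed in wild-type mice and 1, Cry1, was higher by 0.52 in null mice (0 and 0 adjusted over the list alone), with medians of −0.13 and 0.01 (camera adjusted p = 0.507 and 0.945). The call of Cry1 (adjusted p = 0.0447) ended without null 5 °C replicates 1, 2, 4 or 5 or null 28 °C replicates 2, 3, 5 or 6 (adjusted p = 0.0505 to 0.137).

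Other lists passed in the cold, in 1 or both genotypes, with the preset correlation and by fry but not with an estimated correlation. Of 12 interferon response genes, 7 fell in wild-type mice and 0 in null mice (8 and 3 adjusted over the list alone), with medians of −0.44 and −0.23. The list had camera adjusted p = 0.000652 and 0.00197, and adjusted p = 0.128 and 0.186 with an estimated correlation. Usp18 fell by 0.66 on the log2 scale in wild-type mice, and its change of −0.46 in null mice did not pass (adjusted p = 0.0715). Of 13 white-adipocyte and adipokine genes, 1 rose and 3 fell in wild-type mice and 3 fell in null mice (1 and 6, and 0 and 3, adjusted over the list alone). Some of these decreases did not pass without single arrays, such as wild-type 5 °C replicate 1 (limma adjusted p = 0.0648 and 0.141) or null 5 °C replicate 4 (0.0920). Adiponectin Adipoq was at −0.36 and −0.27, and the medians were −0.24 and −0.13, with camera adjusted p = 0.0208 and 0.0649, and adjusted p = 0.288 with an estimated correlation in wild-type mice. Of 15 proliferation genes, 1, Ccna2, rose by 0.52 in wild-type mice and 0 passed in null mice (1 and 0 adjusted over the list alone), with medians of 0.27 and 0.28. The list had camera adjusted p = 0.0117 and 0.0156, and adjusted p = 0.300 and 0.361 with an estimated correlation. The call of Ccna2 ended without wild-type 5 °C replicates 1 (adjusted p = 0.0681) or 2 (0.0696) or wild-type 28 °C replicate 3 (0.0504). Of 9 mast cell markers, 4 fell in wild-type mice and 0 passed in null mice (5 fell and 1 rose, and 0, adjusted over the list alone), with Cpa3 at −0.83 and −0.31 and medians of −0.35 and −0.03. The list had camera adjusted p = 0.00347 and 0.986, and adjusted p = 0.217 with an estimated correlation in wild-type mice.

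The remaining cell type lists did not pass in the cold. Of 10 nerve and Schwann cell markers, 1 rose and 4 fell in wild-type mice and 1 rose and 3 fell in null mice (2 and 4, and 1 and 3, adjusted over the list alone), with S100b at 1.48 and 1.43, Mbp at −0.42 and −0.38 and medians of −0.24 and −0.12 (camera adjusted p = 0.307 and 0.420). Some decreases in wild-type mice did not pass without wild-type 5 °C replicates 1, 2, 3 or 4 or wild-type 28 °C replicates 1 or 2 (limma adjusted p = 0.0556 to 0.0855). A decrease in null mice did not pass without null 5 °C replicates 1, 3 or 4 or null 28 °C replicates 3, 4, 5 or 6 (limma adjusted p = 0.0555 to 0.122). Nor did that decrease pass with array medians subtracted, with the replicate block or with only the groups compared (limma adjusted p = 0.0595 to 0.0728). Of 13 endothelial markers, 1 rose and 1 fell in wild-type mice and 1 fell in null mice (1 and 1, and 0 and 1, adjusted over the list alone), with the receptor Tek at −0.43 and −0.34 and medians of 0.00 and −0.09 (camera adjusted p = 0.681 and 0.171). Of 13 epithelial markers, 0 passed in either genotype, with medians of −0.04 and 0.06 (camera adjusted p = 0.569 and 0.945). The mean and the test of the endothelial list pointed down in wild-type mice, where its median was just above 0. In null mice the mean was −0.03 in the epithelial list and just above 0 in the nerve list, with the opposite sign to the median and the test. The endothelial increase was in Kdr, a receptor of vascular endothelial growth factor, by 0.24 (adjusted p = 0.0425), a call that ended without wild-type 5 °C replicates 1, 3, 4 or 5 or wild-type 28 °C replicates 1 to 4 (adjusted p = 0.0586 to 0.101). Red blood cells had 1 measured gene and were not tested.

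Beside chromosome 15, the chromosome with the most genotype calls was 9, with 7, Lrrfip2, Cmtm8, Stt3b, Clec3b, Lars2, Sacm1l and Fyco1 (odds ratio 2.77, Fisher's exact adjusted p = 0.117 over chromosomes), named after their positions were seen. This test counts calls per whole chromosome. Whether calls gather on shorter stretches of chromosome 9, or of others beside 15, was not tested. In the difference of the cold effects 0 genes passed by limma, with 1137 at an unadjusted p under 0.05, so no gene called here in 1 genotype only is shown to differ between them.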
